A study of Mus musculus with 6 samples.

How the data were processed

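Total RNA of whole testis was hybridised to 6 Affymetrix arrays, 3 from wild-type and 3 from Phf13 knockout mice aged 5 weeks. The values deposited by the authors are log2 values, 1 per probe set, made with Affymetrix Expression Console 1.4.1, per the submitters' processing notes. The log2 scale was read from the values, which have 2 decimals and nearly the same quartiles on every array. Which summarization and normalization the authors chose in that software, and the genome build behind the array's annotation, are not given in the sources used here. The labels call the arrays replicates of a genotype without saying that each came from another animal, so p-values measure only the spread between these samples, which may be technical. No array repeated another: the smallest root mean square difference between a pair was 0.17, and correlations between arrays ran from 0.989 to 0.998.

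The table holds 45101 probe sets. The 64 Affymetrix control probe sets were left out of the tests, and the other 45037 were tested with no filter. Names came from the platform annotation: 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none, and no gene was named from a probe set of the last 2 kinds. Of the first kind, 34741 were found through their gene identifier in the RefSeq table of assembly GRCm38.p6, which changed 0 symbols. The same table gave the gene order on chromosome 4; no coordinates were used. Where a value per gene was needed, the probe set with the highest mean over all 6 arrays stood for the gene, which gave 18193 genes. Genes were placed on chromosomes by the same RefSeq table, through their gene identifier, and probe sets not found in it were given no chromosome.

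Tests were run in R 4.3.3 with limma 3.58.1. The log2 values were fitted with lmFit on genotype and moderated with eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05; every adjusted p of a gene is from this limma fit. Fixed before the data were examined were the groups, this fit, 27 gene lists for cell types, pathways, complexes and the neighbours of Phf13, the alternatives, and the rule for naming genes. Lists and the genes of each of 21 chromosomes were tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists or the chromosomes, and again with an estimated correlation. Lists were also tested with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. Means of a list per array were compared with an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1. A gene called adjusted over the list alone was corrected only for the genes of that list.

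The naming rule took Phf13 and then, among probe sets with 1 symbol, an adjusted p under 0.05 and groups that do not overlap, the 12 genes with the largest rise and the 12 with the largest fall. In all, 16 genes qualified as higher and 12 as lower. Predicted and unnamed symbols were counted and not named. From each list past the set test the 4 genes with the smallest p were named, and at most 2 from any other list. Genes named outside this rule are said to be chosen after their values were seen.

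The procedure was tested on simulated data for the same comparison, with 45037 probe sets. Of changes of 0.5, 1, 2 and 3 on the log2 scale, 16%, 70%, 100% and 100% were recovered, 50 of each having been planted. Of 44797 unchanged probe sets, 8 were called. Of 2 lists shifted by 0.4, 2 were called, and of 25 unshifted lists, 0. The noise was drawn independently for each probe set, with no correlation between genes and no sets of arrays. The simulation therefore cannot show how often camera errs on the real lists, whose estimated correlations reached 0.387. A split of the real arrays that mixes genotypes called up to 7 lists. Apart from the Sertoli list, the lists that passed on the real arrays had medians smaller in size than 0.4.

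Alternatives were the replicate number as a block, runs of consecutive codes in the sample titles as a block, probe sets above the median level only, quantile normalization, median centring, an intensity trend with robust moderation, array weights, each array left out in turn, other thresholds, an unmoderated statistic and the mean of a gene's probe sets. After seeing the data, a block for the 2 sets of arrays told apart by the 18S control probe sets, and a count without the neighbours of Phf13, were added. A fit without wild type 3 and knockout 1 together was also run after seeing the data and not kept, because these arrays were picked by their expression and without them genotype and 18S set are the same. No control probe set passed the threshold for genotype (0 of 64, with 0.453 as the smallest limma adjusted p), and 27 probe sets passed for the difference between the 2 sets, 0 of them among the 45 called for genotype. This does not show that the controls were equal between genotypes. Inside each set, the 18S mean and AFFX-BioB-5_at were lower on every knockout array than on every wild-type array.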

Results

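Phf13 encodes a PHD finger protein that reads methylated histone H3. Gene expression was measured on Affymetrix arrays in whole testis of 5-week-old mice that lacked Phf13 and of wild-type mice. Each genotype had 3 arrays. At this age the testis of a mouse holds spermatogonia, meiotic spermatocytes and spermatids next to Sertoli cells, Leydig cells and other somatic cells, so every value below is a level in mixed tissue. The deposited log2 values ran from 1.42 to 14.01, and the median probe set lay between 5.22 and 5.28 on the 6 arrays. The number of arrays limits the precision. The comparison asks which transcripts differ between knockout and wild-type testis.

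The Phf13 transcript fell by 2.91 on the log2 scale in the knockout, a 7.5-fold lower level. Its only probe set stood at 9.53 ± 0.05 (SD, n = 3) in wild type and at 6.62 ± 0.08 (SD, n = 3) in knockout, with limma's adjusted p = 7.7e-06. All 3 knockout arrays, at 6.71, 6.60 and 6.55, lay below all 3 wild-type arrays, at 9.55, 9.47 and 9.56, so the target gene went with the genotype label on all 6 arrays. Where the probes lie relative to the deleted part of the gene is not given in the sources used here.

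A small number of other transcripts passed the threshold, several with large differences. Atp13a5, a P-type ATPase, rose from 2.49 ± 0.16 to 6.37 ± 0.26 (SD, n = 3 each), a log2 difference of 3.88 with a standard error of 0.15 (limma adjusted p = 3.17e-05). Tas1r1, which encodes a subunit of the umami taste receptor, fell by 3.74 on the log2 scale, from 8.30 ± 0.16 to 4.56 ± 0.11 (SD, n = 3 each; limma adjusted p = 7.7e-06). Of 45037 probe sets tested, 25 were higher and 20 were lower in knockout at an adjusted p under 0.05. These 45 probe sets covered 17 distinct genes that rose and 14 that fell, with 8 probe sets that have no single gene symbol.

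Several of the genes that rose encode membrane transporters. Besides Atp13a5, they included Atp8b4, of the phospholipid-transporting ATPase family, which rose by 2.67 (SE 0.18, limma adjusted p = 0.00161), and Slc22a29, of the organic anion transporter family, which rose by 2.30 (SE 0.21, limma adjusted p = 0.00872). The cationic amino acid transporter gene Slc7a2 rose by 1.18 and the sodium and calcium exchanger gene Slc24a2 by 1.12. Transporters were not a list fixed beforehand, and no enrichment of them was tested. A pair of genes known from synapses, the neuronal pentraxin gene Nptx2 and the vesicle priming gene Unc13c, rose by 1.47 and 1.25. Tmem40 rose by 2.03, Nlrp4a by 1.98, the radial spoke gene Rsph3a by 1.37, Tmed6 by 1.06 and the microtubule-associated gene Mtus2 by 1.02. Many of these genes were dim in wild type: Atp13a5 stood at 2.49 ± 0.16, Nlrp4a at 2.34 ± 0.16 and Slc7a2 at 3.68 ± 0.14 (SD, n = 3 each). The lower quartile of the wild-type arrays lay between 3.66 and 3.72. No background level was used, so the size of a rise from such levels is uncertain. Tmed6 was bright in both genotypes, at 8.90 ± 0.04 in wild type and 9.96 ± 0.25 in knockout (SD, n = 3 each).

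The small heat shock protein gene Hspb7, on chromosome 4 like Phf13, fell by 1.58 on the log2 scale (SE 0.10, limma adjusted p = 0.00125). Its other probe sets fell by 1.32 and by 0.99. The ADP-ribosyltransferase gene Art1 fell by 1.18 and Tnfaip2 fell by 1.14. Smad1, a transducer of bone morphogenetic protein signals, fell by 0.84, from 9.38 ± 0.12 to 8.53 ± 0.09 (SD, n = 3 each). The integrin gene Itga1 fell by 0.80, the lysyl oxidase family gene Loxl1 fell by 0.81, the neuropeptide gene Npb fell by 0.84 and the kinase gene Map4k1 fell by 0.78. Pisd-ps3, a pseudogene, fell by 0.85. Zbtb48, which encodes a zinc finger protein of telomeres, fell by 0.97, and the zinc finger gene Casz1 fell by 0.89. Probe sets of Slc22a29, Tnfaip2 and Pisd-ps3 are of a type in which some probes can bind other transcripts. For 17 of the 25 named genes the array holds other probe sets, 31 in all. Of these, 17 went the same way at an unadjusted p under 0.05, 6 of them past the adjusted threshold, 0 went the opposite way at that p, and 14 had an unadjusted p of 0.05 or more. The other probe sets of Casz1 were split: 1 differed by -0.53, and the rest by -0.03 and 0.05. Some of the 14 had the opposite sign. The only other probe set of Rsph3a differed by -0.19, those of Nptx2 and Atp8b4 by -0.08 each, and that of Itga1 by 0.08.

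**Figure D1:**
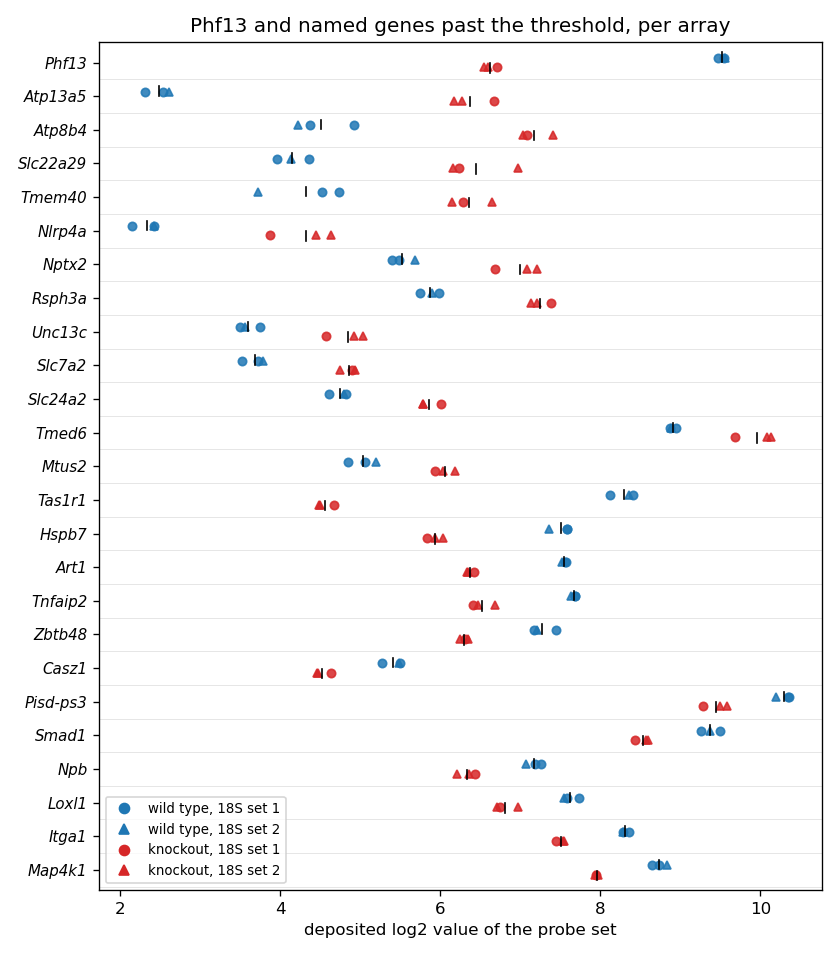
Deposited log2 value of each named gene's probe set (horizontal axis) on each of the 6 arrays, with wild type in blue and knockout in red. Circles and triangles mark 2 sets of arrays told apart by their 18S control probe sets, and black ticks are group means of 3 arrays. Phf13 lies at 9.53 in wild type and 6.62 in knockout, and no gene shown has overlapping groups.

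In all 45 probe sets the 3 knockout arrays and the 3 wild-type arrays did not overlap. Over the whole array, 19.3% of probe sets had groups that did not overlap, against 10% by chance for 3 against 3, and 6812 had an unadjusted p under 0.05, against 2252 by chance. The arrays fell into 2 sets by their 18S ribosomal RNA control probe sets: wild type 1, wild type 2 and knockout 1 averaged 12.35 ± 0.32 on the log2 scale, and wild type 3, knockout 2 and knockout 3 averaged 10.09 ± 0.54 (SD, n = 3 each). The second set was also the last run of consecutive codes in the sample titles. The 3' minus 5' difference of the actin control probe sets, a sign of RNA or labelling quality, was 0.81 ± 0.07 in the first and 0.58 ± 0.02 in the second (SD, n = 3 each). That of Gapdh ran from 0.00 to 0.14 in the first and from -0.27 to -0.20 in the second. Each set held both genotypes. Inside each set, however, the 18S mean was lower in knockout. It was 12.03 against 12.34 and 12.67 in wild type in the first set, and 9.87 and 9.69 against 10.71 in the second. Phf13 differed by -2.80 in the first and by -2.99 in the second. A split of the arrays by these sets, which mixes genotypes, gave 6285 probe sets at an unadjusted p under 0.05. An excess over chance as large as that for genotype is therefore not particular to genotype. With the sets as a block, a fit chosen after seeing the data, 43 probe sets passed, 38 of them among the 45. With the planned block of title code runs, of which the first holds a single array, 12 passed as higher and 4 as lower, and 17 named genes missed the threshold; with array weights, 1654 and 1532 passed. The counts also depended on single arrays: 178 higher and 998 lower passed without wild type 3, and 140 higher without knockout 1. Without wild type 1, wild type 2, knockout 2 or knockout 3, between 8 and 12 passed as higher and between 4 and 8 as lower. Phf13, Atp13a5, Rsph3a, Tas1r1, Hspb7 and Art1 passed in every alternative with a moderated fit that tested them, and the other 19 named genes kept their direction but missed the threshold in 1 to 8 of these. The unmoderated statistic called 0 probe sets higher and 1 lower.

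Genes marking Sertoli cells, the somatic cells that nurse germ cells, rose as a group. All 18 measured genes had a positive difference, with a median of 0.40, and 14 had an unadjusted p under 0.05. The mean of the list was 8.73 ± 0.03 in wild type and 9.10 ± 0.08 in knockout (SD, n = 3 each; exact permutation p = 0.1, the smallest possible for 3 against 3). The genes with the smallest p were Cst12 (0.58), Inhbb (0.41), which encodes a subunit of inhibin B, Fshr (0.45), the receptor for follicle-stimulating hormone, and Aard (0.45), each with an SE of at most 0.11. Each had an adjusted p of 0.00481 adjusted over the list alone; limma's adjusted p over all probe sets ran from 0.144 to 0.157. In all, 13 of 18 genes passed when adjusted over the list alone and 0 over all probe sets. The set test, camera with its preset correlation, gave an adjusted p = 1.23e-11 for the list, and adjusted p = 0.268 with an estimated correlation. The median was 0.32 inside the first set of arrays and 0.37 inside the second.

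The other somatic lists had medians from 0.05 to 0.22, and no test compared these lists with each other. Of 13 genes of peritubular myoid cells and stroma, 12 had a positive difference, with a median of 0.21. The proteoglycan gene Dcn differed by 0.95 (SE 0.17), smooth muscle actin Acta2 by 0.49 (SE 0.10), Pdgfra by 0.55 (SE 0.12) and Tcf21 by 1.00 (SE 0.24). These 4 passed when adjusted over the list alone, had the only unadjusted p under 0.05 in the list, and did not pass over all probe sets. The list rose by the set test (camera adjusted p = 0.00921), with adjusted p = 0.636 with an estimated correlation, but its median was -0.04 in the first set of arrays, with the higher actin 3' minus 5' difference, and 0.58 in the second, and the call was lost without wild type 3 (adjusted p = 0.357; 0.000658 to 0.357 over 15 alternatives). Of 21 genes of macrophages and other leukocytes, 20 were above 0 with a median of 0.22, and none had an unadjusted p under 0.05. Cd3g differed by 0.22, Ptprc by 0.44, Csf1r by 0.35 and Mrc1 by 0.20. This list also rose by the set test (camera adjusted p = 0.00921; adjusted p = 0.674 with an estimated correlation), while its median was -0.14 in that first set and 0.30 in the second. The call was lost without knockout 3 (adjusted p = 0.153) and with the sets as a block (adjusted p = 0.0522), the lowest of 15 alternatives being 9.36e-07. The exact permutation test of list means gave p = 0.4 for leukocytes and 0.2 for myoid cells and stroma. Neither list passed fry (fry adjusted p = 0.420 and 0.303). Leydig cell genes had a median of 0.20 and did not pass (camera adjusted p = 0.155), with Hsd3b1 at 0.56 and Star at 0.49. Of these 11 genes 9 were above 0 and 2 below, and 3 were higher and 1 lower at an unadjusted p under 0.05. Only Hsd3b1 passed when adjusted over the list alone. Inside the sets their medians were -0.08 and 0.18. Over 15 alternatives the median ran from 0.05 without knockout 2 to 0.38 without knockout 1, and the list passed in 2 of them, without knockout 1 and with array weights (adjusted p from 0.0146 to 0.627). Endothelial genes had a median of 0.05 (camera adjusted p = 0.616).

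Genes of other tissue that a dissection can carry were measured beside these. The adipose tissue list of 6 genes rose (camera adjusted p = 0.00921; adjusted p = 0.268 with an estimated correlation), with a median of 0.28 and all 6 above 0. The median was 0.22 in the first set of arrays and 0.24 in the second. The fatty acid binding protein gene Fabp4 differed by 2.21 (SE 0.53) but varied between wild-type arrays, with 5.40 ± 1.14 in wild type and 7.61 ± 0.63 in knockout (SD, n = 3 each). Retn differed by 0.34, Cidec by 0.40 and Adipoq by 0.22. Of the 6 genes, 3 had an unadjusted p under 0.05; these passed when adjusted over the list alone and 0 passed over all in limma. Epididymis genes had a median of 0.04 (camera adjusted p = 0.719) and red blood cell genes a median of 0 and a mean of -0.03 (camera adjusted p = 0.824).

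Immediate early and heat shock genes, which respond to handling of tissue and cells, rose slightly as a group. Of 14 genes, 12 were above 0, with a median of 0.18 (camera adjusted p = 0.0124; adjusted p = 0.268 with an estimated correlation). Fos differed by 0.58 (SE 0.10) and passed when adjusted over the list alone, at 0.00515; no other gene did, and 0 passed over all in limma, with 5 higher and 1 lower at an unadjusted p under 0.05. The call was lost among probe sets above the median level (adjusted p = 0.0606; 0.00899 to 0.0606 over 15 alternatives). Ier2 differed by 0.33 and Hspa1b by 0.37, whereas Dusp1 differed by -0.23. Inside the 2 sets of arrays the medians were 0.10 and 0.16.

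**Figure D2:**
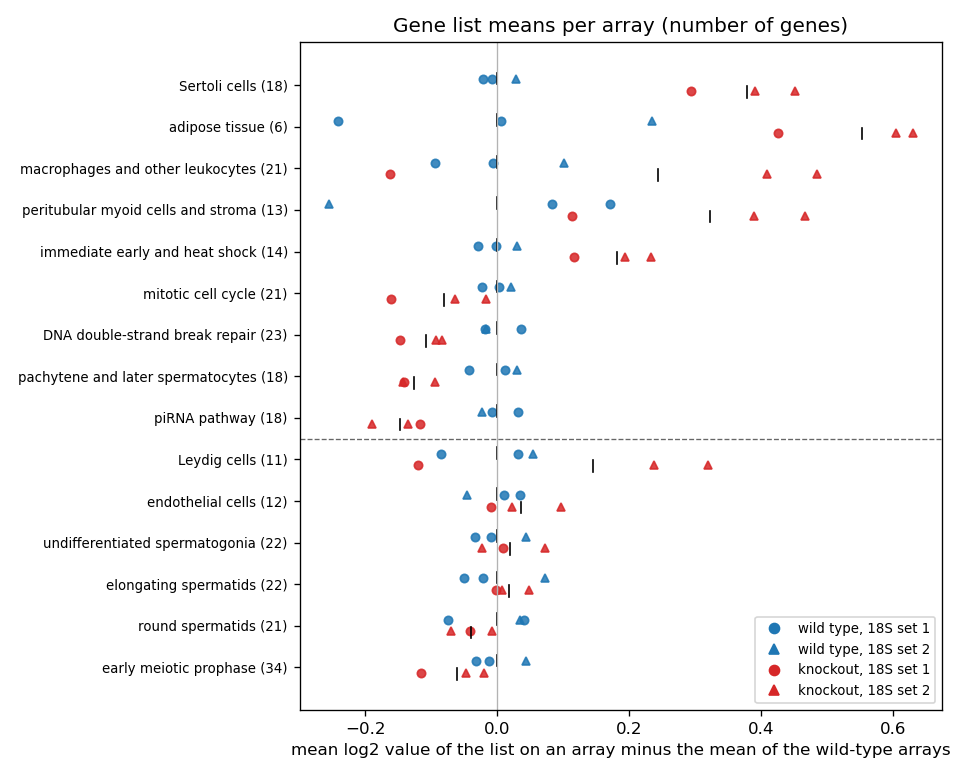
Mean log2 value of each gene list on each array minus the mean of the 3 wild-type arrays (horizontal axis), with wild type in blue and knockout in red and the number of genes in brackets. Circles and triangles mark the 2 sets of arrays told apart by 18S control probe sets, black ticks are group means, and lists above the dashed line passed the set test. The Sertoli list averages 8.73 in wild type and 9.10 in knockout with no overlap, and the macrophage list overlaps.

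Germ cell and cell division genes of 4 lists were lower in knockout, each by a small amount. The piRNA pathway list, whose products silence transposons in germ cells, fell (camera adjusted p = 0.00921; adjusted p = 0.268 with an estimated correlation), with a median of -0.18 and 14 of 18 genes below 0. Piwil2 differed by -0.30 (SE 0.10), Pnldc1 by -0.33 (SE 0.11), Pld6 by -0.22 (SE 0.08) and Tdrd9 by -0.25 (SE 0.10). The list of pachytene and later spermatocytes fell (camera adjusted p = 0.00962; adjusted p = 0.268 with an estimated correlation), with a median of -0.13 and 16 of 18 genes below 0. The meiotic kinase Aurkc differed by -0.42 (SE 0.09), Ccna1, a cyclin of male meiosis, by -0.28, and Piwil1 by -0.26. X-linked Taf7l, by contrast, differed by 0.27. The DNA double-strand break repair list fell (camera adjusted p = 0.0107; adjusted p = 0.364 with an estimated correlation), with a median of -0.12 and 19 of 23 genes below 0. In it Bard1 differed by -0.42 (SE 0.08), Blm by -0.26, Rad50 by -0.27 and Mdc1 by -0.27. The mitotic cell cycle list fell (camera adjusted p = 0.0472; adjusted p = 0.685 with an estimated correlation), with a median of -0.10, Aurkb at -0.39, Plk1 at -0.31, Kif11 at -0.33 and Tk1 at 0.36. Aurkc and Bard1 passed when adjusted over the list alone, and 0 genes of these 4 lists passed over all probe sets in limma. At an unadjusted p under 0.05, 7 genes of the piRNA list, 5 of the spermatocyte list, 5 of the repair list and 3 of the cell cycle list were lower, and 1 spermatocyte gene, Taf7l, was higher. Inside the 2 sets of arrays the medians were -0.14 and -0.13 for the piRNA list, -0.12 and -0.16 for the spermatocyte list, -0.20 and -0.06 for the repair list and -0.16 and -0.06 for the cell cycle list. The piRNA call held in all 15 alternatives, and the cell cycle call was lost in 10 of 15 (adjusted p from 0.019 to 0.209). The repair call was lost without wild type 2 (adjusted p = 0.0692; 0.00272 to 0.0692 over 15 alternatives), and the spermatocyte call among probe sets above the median level (adjusted p = 0.053; 0.00536 to 0.053).

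Genes of spermatids lay near 0. The elongating spermatid list of 22 genes had a median of -0.00 and a mean of 0.02 (camera adjusted p = 0.987), and the round spermatid list of 21 genes had a median of -0.03 (camera adjusted p = 0.479). The elongating list was bright, with a mean of 12.22 in wild type and Prm1 at 13.99, where array maxima ran from 13.98 to 14.01. Whether differences are compressed at such levels was not measured. Undifferentiated spermatogonia had a median of 0.04 (camera adjusted p = 0.686), with Lin28a at -0.43 passing when adjusted over the list alone. Differentiating spermatogonia had a median of 0.09 (camera adjusted p = 0.17), with Rhox13 at 0.33 and Tktl1 at 0.48, both X-linked. Early meiotic prophase had a median of -0.05 (camera adjusted p = 0.104; it passed in 3 of 15 alternatives), with Majin at -0.36 and Spo11, which makes the breaks that start meiotic recombination, at -0.29. Among lists close to the reading of histone marks, the Polycomb list had a median of -0.06 (camera adjusted p = 0.226), the list of H3K4 methyltransferases and demethylases -0.06 (0.481), heterochromatin and H3K9 methylation -0.10 (0.155) and germline histone variants -0.06 (0.561). The median was 0.07 for p53 targets (0.443), 0.12 for the interferon response (0.104), 0.04 for cholesterol synthesis (0.644) and -0.01, with a mean of 0.04, for retinoic acid genes (0.719).

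Over all 27 lists, 9 passed the set test, 5 as higher and 4 as lower, 6 passed fry and 0 passed camera with an estimated correlation, where 5 had an unadjusted p under 0.05. The lists past the set test but not fry were those of myoid cells and stroma, leukocytes and the mitotic cell cycle. Of 458 list members, 32 passed when adjusted over the list alone and 3 over all probe sets in limma, and 48 higher and 51 lower had an unadjusted p under 0.05. The 3 were Tas1r1, Zbtb48 and Camta1, all from the list of genes that neighbour Phf13. That list as a whole did not pass (camera adjusted p = 0.682), with a median of 0.03 and a mean of -0.17. Camera asks for a shift in 1 direction and can miss a list whose genes move both ways. Fry's mixed test, which counts changes in either direction, gave the list an adjusted p = 7.27e-05, the smallest of the 27. Several other lists were also under 0.05 in it. Of the 23 neighbours, 2 passed as higher and 3 as lower when adjusted over the list alone.

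Genes near Phf13 on chromosome 4, but not those directly beside it, were among those that passed. In the gene order of assembly GRCm38.p6, Zbtb48 is the gene 2 places from Phf13 and Tas1r1 the gene 3 places from it, on the same side. Camta1, 14 places away on the other side, rose by 1.01 (SE 0.11, limma adjusted p = 0.0169) by 1 of its probe sets, while its others differed by -0.27, -0.13 and -0.12. Casz1, 76 places away on that side, fell by 0.89. The genes next to Phf13 on either side did not pass: Thap3 differed by 0.14 and Klhl21 by -0.46. Thap3, Klhl21 and Camta1 were picked for their place after their values were seen. Of the 294 probe sets of the neighbours (200 annotated genes on one side and 144 on the other, where the chromosome ends), 4 passed, a share of 1.36%, against 32 of 34650 for other named genes, 0.0924% (Fisher's exact test, two-sided, p = 0.000234). This test was chosen after the calls were seen, and probe sets of a gene are not independent. Of the 23 genes of the list fixed beforehand, 3 passed, against 21 of 18169 other genes with 1 probe set each (Fisher's exact test, two-sided, p = 3.51e-06), a test also chosen after the calls were seen.

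**Figure D3:**
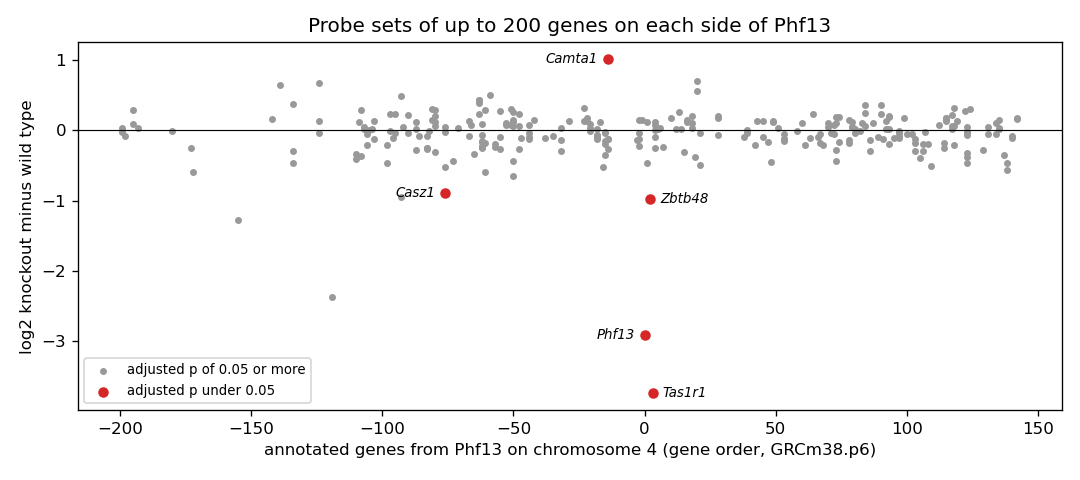
Log2 difference of knockout minus wild type (vertical axis) for each probe set of the annotated neighbours of Phf13 on chromosome 4, against their place in gene order (horizontal axis, in genes from Phf13). Red points passed the adjusted threshold: besides Phf13, Tas1r1 (-3.74), Zbtb48 (-0.97), Casz1 (-0.89) and Camta1 (1.01).

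The widest change was on the X chromosome, where the level of most genes was higher in knockout. Of 617 X-linked genes, 553 (89.6%) had a positive difference, with a median of 0.27, and 284 were higher and 1 was lower at an unadjusted p under 0.05. Of 17404 autosomal genes, 8703 had a positive difference, with a median of 0.00. The X-linked genes rose as a set (camera adjusted p = 8.31e-29; adjusted p = 0.295 with an estimated correlation). Their mean was 5.92 ± 0.05 in wild type and 6.19 ± 0.10 in knockout (SD, n = 3 each; exact permutation p = 0.1, the smallest possible), and every knockout array lay above every wild-type array. No X-linked gene passed in limma over all probe sets, and 166 passed, all of them higher, when adjusted over the chromosome alone. Predicted and unnamed symbols left out, the genes with the smallest p, named after their values were seen, were Tex13a (0.58, SE 0.08), the RNA export factor gene Nxf3 (0.52, SE 0.08), Pwwp3b (0.62, SE 0.11) and Ppp1r2-ps9 (0.56, SE 0.10), each with an adjusted p of 0.0276 over the chromosome alone. The median difference was 0.19 in the first set of arrays and 0.28 in the second, and 0.24 with the sets as a block.

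The 9 measured genes of the Y chromosome also rose as a set, with a median of 0.29 and all 9 above 0 (camera adjusted p = 0.000285; adjusted p = 0.253 with an estimated correlation). Eif2s3y, a translation factor gene, differed by 0.28 (SE 0.10), and Uty, a histone demethylase family gene, by 0.33 (SE 0.12); they were named after their values were seen, and neither passed over all probe sets. The mean of the 9 genes was 6.30 ± 0.04 in wild type and 6.58 ± 0.04 in knockout (SD, n = 3 each; exact permutation p = 0.1). The median was 0.38 in the first set of arrays and 0.16 in the second. With the mean of each gene's probe sets the median was 0.13 (adjusted p = 0.0164; 0.000103 to 0.0164 over 15 alternatives). None of the 19 autosomes passed camera, 0 had an unadjusted p under 0.05 with a preset or an estimated correlation, and the smallest adjusted p was 0.783, so chromosome 4, which carries Phf13, did not shift as a whole (median of -0.00). With 1 probe set per gene, however, chromosome 4 held 2 genes called higher and 4 called lower, Phf13 among them, the most of any chromosome. Hspb7 and Slc24a2 are also on it, outside the neighbours counted above. Whether they are linked to the targeted allele was not tested.

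**Figure D4:**
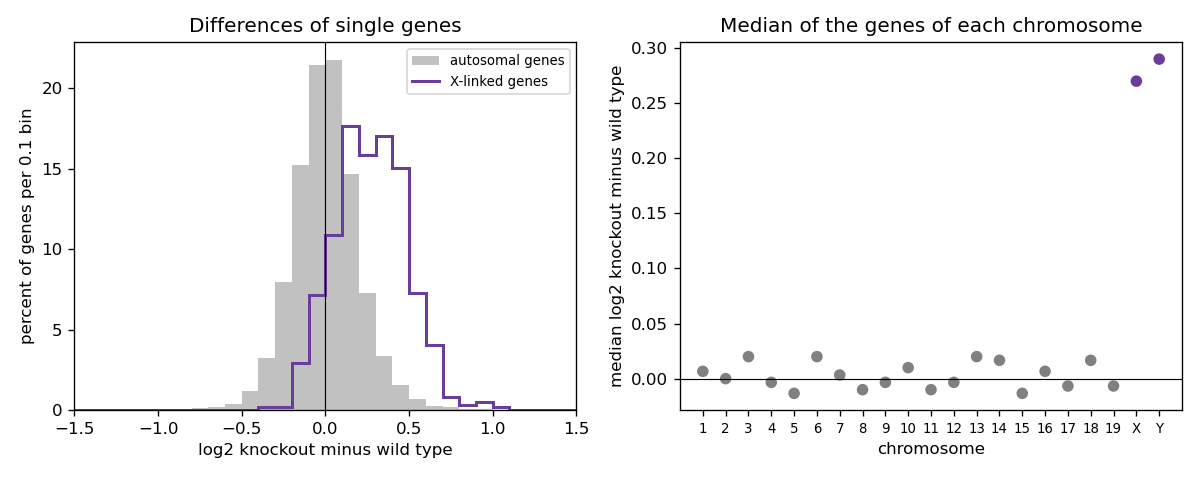
Left, percent of genes (vertical axis) in each bin of 0.1 of the log2 difference of knockout minus wild type (horizontal axis), for X-linked genes (line) and autosomal genes (grey). Right, median log2 difference of the genes of each chromosome, 0.27 for X and 0.29 for Y, with all autosomes near 0.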

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

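The block for the 18S sets and the count without the neighbours of Phf13 were chosen after seeing the data; the other alternatives were planned. The X and Y shifts and the Phf13 difference (-2.95 to -2.87) kept their direction and their side of the threshold in every moderated alternative with the preset correlation that gave them, no called result reversed, and 6 to 10 lists passed the set test. Of the 9 lists past the set test, 3 passed in every such alternative (Sertoli, adipose, piRNA) and 6 missed the threshold in some. With an estimated correlation, however, camera called none of the 27 lists (smallest adjusted p = 0.268, shared by 5 lists, Sertoli, adipose and piRNA among them), with 5 at an unadjusted p under 0.05, and neither X (adjusted p = 0.295) nor Y (0.253). Counts of probe sets did not hold, and the cause was not tested except where named. With the replicate block, 22 passed as higher and 6 as lower, and 1 list member passed. The numbers share no stated origin: deviations of same-numbered arrays correlated at 0.26, 0.07 and 0.12, and wild type 3 correlated best with knockout 2 (0.13), not with its own number, so the block is no paired design. With title code runs as a block, 12 passed as higher, 4 as lower and 1 list member. Probe sets above the median level gave 42 lower, with fewer sets tested. An intensity trend with robust moderation gave 66 higher, 44 lower and 7 list members, and array weights 1654, 1532 and 55. At an adjusted p under 0.1, 48 were higher and 52 lower; at an unadjusted p under 0.05 and 1.5-fold, 301 and 448; the unmoderated statistic, with few residual degrees of freedom, gave 0 and 1. Leaving out 1 array gave 8 to 178 higher, 4 to 998 lower and 1 to 9 list members. The counts grew without wild type 3 (178, 998 and 9 list members) and without knockout 1 (140 higher, 26 lower, 7 list members), which leave 1 genotype in an 18S set by construction; they shrank without wild type 1 (10 and 7), wild type 2 (8 and 4), knockout 2 (12 and 8) and knockout 3 (9 and 4), which also have fewer arrays. Array weights were lowest for knockout 1 (0.383) and wild type 3 (0.601). Without the neighbours of Phf13, 0 list members passed, since the 3 are neighbours. A pseudocount was not run because the values are already log2. Scaling moved the median of all probe sets by at most 0.004. No background level was used, so how far dim probe sets such as those of Atp13a5 and Nlrp4a lie above background was not measured.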

Other observations

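The tests of the places of the calls, of dimness, of the 2 sets of arrays and of Sertoli against other somatic genes were chosen after their results were seen, as was that of stages. The 2 X-linked lists that follow, and the test on them, were chosen after the X shift, the set tests of the planned spermatogonia and spermatid lists and the value of Tex13a were seen. X-linked genes picked as known from spermatogonia, of which Tex11 and Taf7l also stand in the planned lists of meiotic cells, were higher in knockout: all 15 measured had a positive difference, with a median of 0.29, against 0.07 for 32 autosomal genes of spermatogonia, and 9 of the 15 had an unadjusted p under 0.05. Magea5 differed by 0.85 (SE 0.23), Mageb16 by 0.61 (SE 0.13), Tex13a by 0.58 (SE 0.08) and Dmrtc1a by 0.44 (SE 0.11). X-linked genes known from spermatids were higher too: 7 of 8 had a positive difference, with a median of 0.50, against -0.01 for 41 autosomal genes of spermatids. Actrt1 differed by 0.62 (SE 0.13), Zcchc13 by 0.51 (SE 0.10), Cypt3 by 0.48 (SE 0.09) and Cypt1 by 0.43 (SE 0.09), whereas Akap4, among the brightest at 12.35 in both genotypes, differed by 0.00. The X-linked medians exceeded the autosomal ones by 0.22 (permutation over genes, two-sided, p = 0.00075) and by 0.50 (p = 1e-05, the smallest the permutations can give), with adjusted p = 0.00075 and 2e-05 over these 2 tests. Without Tex13a the first list exceeded by 0.21 (permutation p = 0.00075), and without Tex11 and Taf7l by 0.26 (p = 2e-05), with a median of 0.33 over 13 genes. Genes are not independent replicates, so these p-values describe the lists on these arrays. Inside the 2 sets of arrays the medians were 0.25 and 0.24 for the first list and 0.48 and 0.35 for the second.

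The higher level of X-linked genes is a pattern that dimness of their probe sets cannot account for: none of 10000 lists of autosomal genes matched on level reached the X-linked median (permutation p = 1e-04 over random lists, the smallest the draws can give), the highest reaching 0.04. A split between the 2 sets of arrays is argued against as the whole cause, since the median was positive in both, 0.185 at the lower. Other technical differences stay open. The control probe set AFFX-MURINE_b1_at stood at 12.27 and 12.25 in wild type 1 and wild type 2, but at 10.33 in knockout 1. The median inside that first set therefore cannot tell genotype from such a difference. In the second set this control ran from 9.85 in wild type 3 to 10.33 in knockout 3, and the X-linked median was 0.275. X-linked genes of spermatogonia exceeded autosomal ones by 0.218. This would argue against a larger share of RNA from Sertoli and other somatic cells as the whole cause only for genes confined to germ cells. The cells that express each gene of that list were not measured, and the list was picked after the X shift was seen. A part for somatic RNA stays open. A shift in the germ cell stages present would move X-linked and autosomal genes alike only if both were expressed in the same stages. Which stages express each gene was not measured, and the list of pachytene and later spermatocytes fell, with a median of -0.128. X-linked genes exceeded autosomal ones by 0.258 for spermatogonia, without Tex11 and Taf7l, and by 0.50 for spermatids. Both X-linked lists were picked after most X-linked genes had been seen to be higher. These differences therefore cannot decide on stages as the whole cause. These lists were not matched on level, so the sizes of the differences are uncertain. The elongating spermatid list averaged 12.22 in wild type, with Prm1 at 13.99, against array maxima of 13.98 to 14.01. Whether values near the maximum are compressed was not measured. Among bright X-linked genes of spermatids, Akap4 (12.35) differed by 0.00 and Cypt3 (11.62) by 0.48. Undifferentiated spermatogonia genes averaged 5.33, and X-linked Dmrtc1a stood at 9.04. Stages as the whole cause or a part of it, finer stages inside these lists and how genotype would act on sex-linked genes stay open.

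The rise of Sertoli markers was set against the other 4 somatic lists, which a lower share of germ cells would raise alike. Sertoli markers exceeded endothelial markers by 0.343 in their means (permutation over genes, two-sided, adjusted p = 4e-05), Leydig markers by 0.23 (adjusted p = 0.0148) and leukocyte markers by 0.14 (adjusted p = 0.0148), but myoid and stromal markers by only 0.0561 (adjusted p = 0.557). The endothelial genes were dimmer than the Sertoli genes (mean level 5.43 against 8.92), and for the bright Leydig list the difference of list means barely parted the arrays (0.684 as the lowest in knockout, 0.676 as the highest in wild type). A lower share of germ cells and a change in Sertoli cells therefore both stay open. The 2 sets of arrays do not account for the rise, with a within-set median of 0.32 at the lower. Other technical differences between arrays stay open here too.

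The probe sets that passed near Phf13 may belong to a chromosome segment carried with the targeted allele, as when a mutation is made in cells of one strain and bred into another. Passing was more frequent among neighbours than elsewhere (odds ratio 14.9, p = 0.000234 by Fisher's exact test), with 1 probe set higher and 3 lower, but this test restates the observation that prompted it and cannot decide for a segment. Sequence variants under single probe sets remain open: of the 6 other probe sets of these genes, 16.7% went the same way at an unadjusted p under 0.05, 1 of Camta1 went the opposite way, and Tas1r1 and Zbtb48 have no other probe set. An effect of the targeted allele on nearby transcripts also stays open and was not tested.

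Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split called 45 probe sets against at most 4 in another split, so 1 of the 10 splits called as many. It called 9 lists against at most 7, again 1 of 10, and 2 chromosomes against at most 2, a number reached by 2 of the 10. The split by 18S set called 4 probe sets, 6 lists and 1 chromosome, and had 6285 probe sets at an unadjusted p under 0.05, against 6812 for genotype and 495 to 2438 for the other splits that mix genotypes, which points to a structure of the samples besides genotype. That split had an X median of 0.19 and a Sertoli median of 0.18, against 0.27 and 0.40 for genotype; with genotype in the fit, the second set of arrays exceeded the first by a median of 0.12 for X-linked and 0.06 for Sertoli genes. On the first principal component, with 45.6% of the variance, wild type 3 lay at 4.47 and knockout 1 at 7.13, between the other wild-type arrays (-40.6 and -27.3) and the other knockout arrays (24.9 and 31.4).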
